A study of Mus musculus with 8 samples.

How the data were processed

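Gene expression was measured in RAW264.7, a mouse macrophage line, with 1-colour (Cy3) whole-genome oligonucleotide arrays. Total RNA from 8 cultures was hybridised to 8 arrays, 1 array per condition. Cultures received melatonin at 1 mM for 1 h or none, and then LPS from Escherichia coli at 100 ng/ml for 1, 3 or 5 h; 1 culture of each arm received no LPS. The 8 arrays were named here by arm and hours of LPS. Groups followed the sample titles, which the descriptions and source names repeat. The treatment field gave LPS times 1 step later than the titles for 3 of the 4 melatonin samples, and no treatment for the melatonin sample at 5 h. The titles were checked against the values of 1887 genes. The melatonin arrays at 0, 1 and 3 h were set against the arrays without melatonin of the titled and the next time. Each correlated more with that of its titled time (r = 0.888 against 0.432 without LPS, 0.725 against -0.585 at 1 h, and 0.719 against 0.634 at 3 h). The 3 h array without melatonin, though, correlated alike with the melatonin arrays at 3 h (0.7186) and 5 h (0.7189). The 1887 genes differed by at least 2 log2 from the array without LPS in the arm without melatonin. Values were centred per gene within an arm, and genes are not independent replicates.

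Per the file headers, the intensity values were processed signals of Agilent Feature Extraction 12.0.3.1 (1-colour protocol, design 074809), with background subtracted, spatial and multiplicative detrending applied, and surrogate values for spots near background. The deposited log2 table of the series held 62976 spots per array and the same sorted values on all 8 arrays, as quantile normalization leaves them; it correlated with the log2 processed signals at r = 0.999 or above, and the tool that made it is not given in the sources used here. Other columns used were, per the file headers, flags of 0 or 1 set by the scanner software for spots well above background, saturated spots and outlier spots. Scanner intensity in the mean spot and local background columns, deposited without further correction, served 1 alternative only. Probe coordinates are those of the files, on mouse build mm9.

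The values compared were log2 processed signals minus the 75th percentile of each array. Control spots (3671 of 62976) and outlier spots were left out, and spots of a probe were averaged, which gave 56605 probes. Symbols of the files were updated through RefSeq accessions for 1535 probes; 32994 probes matched an accession and 10314 carried no symbol. A probe entered if it was well above background on at least 2 of 8 arrays (30417 probes), and the probe with the highest mean stood for its gene, which left 20076 genes. No spot was saturated. The 75th percentile of the signal was 830.1, 793.8, 688.6 and 659.1 at 0, 1, 3 and 5 h without melatonin, and 846.1, 823.4, 793.9 and 718.7 with it. Between 46.96% and 52.99% of probes were well above background. The number of arrays limits the precision.

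R 4.3.3, limma 3.58.1 and data.table (1.17.8) were used. No condition had a replicate. An additive limma model with LPS time (4 levels) and melatonin, empirical Bayes with an intensity trend and 3 residual degrees of freedom, gave the change at 1, 3 and 5 h of LPS (2 arrays against the 2 without LPS) and the melatonin difference (4 arrays against 4, matched by time). A model with a further melatonin by LPS term (2 residual degrees of freedom) gave the melatonin by LPS term, which is the mean melatonin difference at 1, 3 and 5 h minus that without LPS. All tests were moderated limma tests, 2-sided, called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Counts "over the list alone" adjust these p-values within 1 list and comparison, with no correction between lists. That adjustment was not part of the tests fixed beforehand. The p-values measure only the spread between these arrays, which in the additive model holds any melatonin effect that changes with time. Differences at a single time are values without a test. No paired analysis of replicates was possible because each condition has 1 array. The median log2 of all genes moved by less than 0.1 between the 75th percentile and quantile scalings.

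Gene lists (31) were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over lists and comparisons, where at least 5 members were measured (25 lists, 125 tests), and again with an estimated correlation. At single times the list median was placed among 10000 random lists of the same size matched on mean level in 20 bins. Their range reflects the draw of genes and holds no spread between arrays. The lists were immediate early genes, NF-kB feedback genes, cytokines, chemokines, interferon response genes, genes of nitric oxide, prostaglandin and antimicrobial products, Toll-like receptor signalling, NRF2 targets, melatonin receptors and synthesis, circadian clock, AHR targets, cAMP/CREB targets, chaperones of the unfolded protein response, ATF4 stress targets, heat shock genes, cholesterol synthesis, LXR targets, G2/M and G1/S cell cycle genes, hypoxia and glycolysis, p53 targets, IL-4 type macrophage genes, macrophage identity, osteoclast, T cell, B cell, dendritic cell, fibroblast and epithelial markers, ribosomal proteins and housekeeping genes. Camera called 69 of the 125 tests with the preset correlation and 0 with an estimated one. In simulated data a list of cytokines shifted 2-fold was called in 20 of 20 runs with the preset correlation and in 0 of 20 with the estimated one. With the preset correlation 6 of 2480 other tests were called. Simulated genes were drawn independently of each other. The few false calls therefore do not show how the preset correlation fares where members move together, as G2/M genes do (estimated correlation 0.92).

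Named genes followed a fixed rule. A panel of inflammatory genes was given whatever its values. To it were added the 6 called genes with the largest rise and the 6 with the largest fall at each LPS time, the 12 each way for melatonin, up to 4 called members of each list and comparison, 4 each way at each single time, and for the melatonin by LPS term the 10 largest called or, with fewer than 5 called, the 5 largest values. Genes without a symbol, or with a predicted-gene name, were only counted. A few genes that the rule selects are not reported here. Fold bounds ("at least") replace fitted folds where no probe of the gene was well above background on any array of a group. Where only some arrays of a group had such a probe, a fitted value is of uncertain size. The comparisons, their statistical tests, lists, naming rule and all alternatives but 1 were fixed before the data were examined. The alternatives were normexp background correction (offset 50), quantile normalization, the deposited log2 table, no filter, well above background on all 8 arrays, the mean over a gene's probes, no intensity trend, a melatonin by LPS term, melatonin by hours of LPS as a slope, a 2-fold threshold and each array left out in turn. With 1 array of a time left out, the other array of that time adds nothing to the melatonin difference in the additive model. Leaving out either array of a time thus removes the same pair, and the 8 such fits are removals of 4 pairs. A common floor of -4.025 log2 under all values was added after the data were seen, and so was the limit of the 2-fold counts between arms to genes well above background on both arrays.

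The code was tested on simulated data with 200 of 20076 genes changed per run in 5 runs. Of genes changed 2-fold it recovered 38.7% at 1 h of LPS, 41.9% at 3 h, 43.5% at 5 h, 60.3% for melatonin and 0% for melatonin by LPS; of genes changed 4-fold it recovered 75.4%, 79.4%, 75.6%, 87.9% and 26.4%. Unchanged genes had an unadjusted p under 0.05 in 5.3% to 5.61%.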

Results

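Transcript levels were measured in RAW264.7 mouse macrophages on 8 arrays. An arm with melatonin and an arm without were each sampled without LPS and after 1, 3 and 5 h of LPS, the cell wall component of Gram-negative bacteria that Toll-like receptor 4 detects. Each condition has 1 array, so each LPS time compares 2 arrays with the 2 arrays without LPS, and melatonin compares 4 arrays with 4. No array without LPS is matched to each LPS time, so LPS cannot be told apart from hours in culture. Each LPS time also had its own slide column in both arms, so LPS cannot be told apart from slide column either. The layout asks how macrophages respond to LPS over time and how melatonin alters their transcripts with and without LPS. Of the 20076 genes tested, between 17011 and 17996 were well above background on both arrays of a time. Changes are given as log2 with their standard error (SE) and adjusted p. Every named gene called at 1 h (48), 3 h (115) and 5 h (121) of LPS changed the same way in both arms. For the 6 largest rises and 6 largest falls at each time the naming rule required this. The other calls rest on the mean change over both arms, and a test of that mean favours a shared direction. On mm9 the probes lie at chromosome 17, 35336795 to 35336854 for Tnf, and at chromosome 5, 30346367 to 30346426 for Il6. Those of Ccl2 lie at chromosome 11, 81850650 to 81850709, at chromosome 11, 78773567 to 78773626 for Nos2, and at chromosome 4, 11101174 to 11101233 for Trp53inp1.

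After 1 h of LPS, immediate early transcription factors and the earliest inflammatory mediators were up. Egr2, a zinc finger factor of the immediate early class, rose by 6.26 log2 (SE 0.33, adjusted p = 0.00135) and Egr3 by 5.50 (SE 0.42, adjusted p = 0.00481). Cxcl2, a neutrophil-attracting chemokine, was at least 346-fold higher (adjusted p = 0.000226), and Cxcl10, which attracts T cells, rose by 6.13 (SE 0.40, adjusted p = 0.00261). Tnf, the central early cytokine of macrophages, rose by 4.52 (SE 0.19, adjusted p = 0.000603), and Ptgs2, the inducible cyclooxygenase, by 5.29 (SE 0.28, adjusted p = 0.0014). Phlda1 rose by 5.48 (SE 0.14, adjusted p = 0.000211) and Dusp5, a phosphatase that turns off ERK kinases, by 5.31 (SE 0.18, adjusted p = 0.000397). Genes that restrain the response rose with them, among them Nfkbia, the inhibitor of NF-kB (2.68, SE 0.06, adjusted p = 0.000192), and Socs3, which blocks cytokine signalling (3.54, SE 0.18, adjusted p = 0.00124). The chemokine Ccl4 (4.12, adjusted p = 0.00257), the NF-kB adaptor Traf1 (3.66, adjusted p = 0.00209), and the itaconate enzyme Acod1 (3.39, adjusted p = 0.0014) rose as well. So did the phosphodiesterase Pde4b (3.37, adjusted p = 0.00273) and Insig1, a brake on sterol synthesis (1.68, adjusted p = 0.00192).

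By list, 14 of 20 immediate early genes rose at 1 h (19 adjusted over the list alone), with a median of 3.40 log2 (camera adjusted p = 2.74e-29, adjusted p = 0.475 with an estimated correlation). Of 20 NF-kB feedback genes 16 rose (18 adjusted over the list alone; median 1.67, camera adjusted p = 5.31e-25, adjusted p = 0.475 with an estimated correlation). Of 21 cytokines 7 rose (10 over the list alone, camera adjusted p = 8.4e-10), and of 15 chemokines 6 (8 over the list alone, camera adjusted p = 5.89e-09), both with adjusted p = 0.475 with an estimated correlation. Genes of nitric oxide, prostaglandin and antimicrobial products had 2 of 15 raised (5 raised and 1 lowered over the list alone, camera adjusted p = 0.000362), with adjusted p = 0.475 with an estimated correlation. Toll-like receptor signalling had 2 of 24 (7 over the list alone, camera adjusted p = 0.000126, adjusted p = 0.475 with an estimated correlation). Interferon response genes, a later group, had 1 of 37 raised, Oasl1 (adjusted p = 0.0342, up to 0.15 with an array left out), also 1 over the list alone, with a median of -0.03, a mean of 0.12 and camera adjusted p = 0.839. Of 21 genes of cholesterol synthesis 4 rose, among them Insig1, and Idi1 and Hsd17b7, which lost the call under most alternatives (8 over the list alone, camera adjusted p = 0.000203, adjusted p = 0.475 with an estimated correlation). With the common floor the raised genes numbered 9 of 20 immediate early, 4 of 20 NF-kB feedback, 1 of 21 cytokine, 3 of 15 chemokine and 1 of 21 cholesterol synthesis genes, and with normexp 4 of 21 cytokines.

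Some panel genes were not called at 1 h. Il6 and Il12b had adjusted p = 0.334 and 0.391, Il1a 0.219 and Ifnb1 0.0897, all near background without LPS. At 1 h Ifnb1 was well above background in both arms, and Il6, Il1a and Il12b in the arm without melatonin only. Nos2, the inducible nitric oxide synthase, stood at 0.98 log2 (adjusted p = 0.0537), Hmox1 at 0.43 (adjusted p = 0.106), Irf7 at -0.06 (adjusted p = 0.934) and Irf1 at -0.82 (adjusted p = 0.675). Il1b rose by 4.59 (SE 0.49, adjusted p = 0.0138), Nfkbiz by 5.14 (SE 0.44, adjusted p = 0.00725), Tnfaip3 by 3.90 (SE 0.39, adjusted p = 0.0105), and Egr1 by 5.60 (SE 0.54, adjusted p = 0.00979). Among chemokines, Cxcl2, Cxcl10 and Ccl4 had the larger rises given above, with Ccl3 at 3.21 (adjusted p = 0.00777), Ccl2 at 1.79 (adjusted p = 0.0372) and Ccl5 at 0.83 (adjusted p = 0.0236). The largest falls were Lncpint by 1.80, Kifc1 by 1.70, Txnip, a brake on glucose uptake, by 1.45, D10Bwg1070e by 1.29, Snhg20 by 1.23 and Fbxo5, an inhibitor of the anaphase-promoting complex, by 1.22. These 6 lost the call without the 1 h array of the arm without melatonin, and their highest adjusted p with 1 array left out was 0.12, 0.098, 0.154, 0.168, 0.0651 and 0.0812. Leaving out the same array ended the calls of Il1b, Nfkbiz, Tnfaip3, Ccl2 and Ccl5, whose highest adjusted p was 0.055, 0.066, 0.0981, 0.221 and 0.182, and other arrays did so for all of these but Nfkbiz. The array without LPS or melatonin did so for Egr1 (0.0625) and Ccl3 (0.0505). The common floor ended all of these 7.

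At 1 h limma called 393 of 20076 genes, 336 raised and 57 lowered, with 242 and 31 of them at least 2-fold. In all, 2999 genes had an unadjusted p under 0.05 where chance gives 1004. The count was 95 without the 1 h array and 137 without the 0 h array of the arm without melatonin, and 143 without the 1 h array with melatonin. It was 173 without either 3 h array, 226 and 230 without the 5 h arrays without and with melatonin. Of the settings, it was 137 with no filter, 98 with the common floor and 159 with no intensity trend. Of the 48 named calls 15 held under every alternative, those of Cxcl2, Cxcl10, Nfkbia, Ptgs2, Tnf, Egr2, Egr3, Phlda1, Dusp5, Traf1, Socs3, Ccl4, Acod1, Pde4b and Insig1.

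By 3 h many secreted mediators were up. Il6, the acute-phase cytokine, was at least 302-fold higher (adjusted p = 0.00197), the colony-stimulating factors Csf3 and Csf2 at least 167-fold and 108-fold (adjusted p = 0.000871 and 0.0012). Il1a was at least 89.0-fold higher (adjusted p = 0.00173), the type I interferon Ifnb1 at least 64.2-fold (adjusted p = 0.00308) and Cxcl2 at least 1290-fold (adjusted p = 6.66e-05). Cxcl10 rose by 9.04 log2 (SE 0.40, adjusted p = 0.000215), Ptgs2 by 8.60 (SE 0.28, adjusted p = 0.000132) and Il1b by 7.90 (SE 0.49, adjusted p = 0.000545). Rsad2, an antiviral interferon-induced enzyme, rose by 7.33 (SE 0.67, adjusted p = 0.00145). Ccl5 rose by 6.06 (SE 0.10, adjusted p = 1.73e-05) and Tnf by 5.31 (SE 0.19, adjusted p = 0.000143). Ccl2, the monocyte attractant, rose by 5.04 (SE 0.27, adjusted p = 0.000363) and Nos2 by 3.76 (SE 0.17, adjusted p = 0.000216). The feedback genes Socs3 (5.12), Nfkbiz (5.12), Tnfaip3 (4.78) and Nfkbia (3.13) stayed up. Stress genes under ATF4 also rose, with Chac1, a glutathione-degrading enzyme, at 3.33 (adjusted p = 0.000267) and Trib3, a pseudokinase, at 2.63 (adjusted p = 0.000182).

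Falls at 3 h took in cell cycle genes and single genes of other functions. Hpgd, which degrades prostaglandins, was at least 24.6-fold lower (adjusted p = 0.00315), Rnf144b at least 21.1-fold (adjusted p = 0.002) and Pik3ip1, an inhibitor of PI3-kinase, at least 10.1-fold (adjusted p = 0.00148). Klhl30 fell (adjusted p = 0.00107), with 1 of 2 arrays at 3 h well above background, Angptl4, an inhibitor of lipoprotein lipase, by 4.45 log2 (SE 0.42, adjusted p = 0.00158) and Kbtbd11 by 4.41 (SE 0.55, adjusted p = 0.00349). The cholesterol exporter Abcg1 fell by 3.68 (SE 0.21, adjusted p = 0.00045), and the p53 target Trp53inp1 by 3.70 (SE 0.25, adjusted p = 0.000697), a call that ended among genes above background on all 8 arrays. Of 22 G2/M genes 16 fell and 0 rose (19 fell adjusted over the list alone; median -0.86, camera adjusted p = 1.29e-07, adjusted p = 0.566 with an estimated correlation), with the proliferation marker Mki67 down by 1.31. Of 21 G1/S genes 14 fell and 0 rose (19 fell over the list alone; median -0.88, camera adjusted p = 3.81e-07, adjusted p = 0.475 with an estimated correlation), with E2f2 down by 3.28.

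At 3 h 18 of 21 cytokines rose (20 over the list alone; median 3.78, camera adjusted p = 2.25e-09), 12 of 15 chemokines (13; median 5.38, camera adjusted p = 1.3e-08) and 19 of 20 NF-kB feedback genes (19; median 2.66, camera adjusted p = 7.39e-12), each with adjusted p = 0.475 with an estimated correlation. So did 14 of 20 immediate early genes with 1 lowered (15 and 2; median 2.27, camera adjusted p = 3.15e-05, adjusted p = 0.475 with an estimated correlation). Of 37 interferon response genes 20 rose (20 over the list alone; median 1.45, camera adjusted p = 3.81e-07, adjusted p = 0.597 with an estimated correlation). Genes of nitric oxide, prostaglandin and antimicrobial products had 11 of 15 raised and 1 lowered (12 and 1; median 1.85, camera adjusted p = 4.98e-05, adjusted p = 0.475 with an estimated correlation). Toll-like receptor signalling had 13 of 24 raised and 1 lowered (14 and 2; median 0.56, camera adjusted p = 0.00233) and ATF4 targets 8 of 16 raised (10; median 0.56, camera adjusted p = 0.00155), both with adjusted p = 0.475 with an estimated correlation. In the panel, Hmox1 stood at -0.24 (adjusted p = 0.107), Irf1 at 0.60 (adjusted p = 0.543), Irf7 at 0.24 (adjusted p = 0.391), and Il12b was at least 1.19-fold higher (adjusted p = 0.0735). Limma called 6766 genes at 3 h, 3735 raised and 3031 lowered (55.2% raised), or 2744 and 3657 (42.9% raised) with quantile normalization, and 1098 and 1282 of the 6766 changed at least 2-fold. The count was 2489 without the 0 h array and 2590 without the 3 h array of the arm without melatonin.

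At 5 h the mediators of 3 h stayed high. Ptgs2 reached 9.59 log2 (SE 0.28, adjusted p = 7.4e-05), Il1b 8.82 (SE 0.49, adjusted p = 0.00029), Cxcl10 8.66 (SE 0.40, adjusted p = 0.000183) and Rsad2 7.47 (SE 0.67, adjusted p = 0.000856). Lcn2, which binds bacterial iron carriers, rose by 7.44 (SE 0.47, adjusted p = 0.000381) and Saa3, an acute-phase protein, by 6.32 (SE 0.66, adjusted p = 0.00139). Ccl5 rose by 6.54 (SE 0.10, adjusted p = 8.31e-06) and Ccl2 by 6.56 (SE 0.27, adjusted p = 0.000132). Cxcl2 was at least 1900-fold, Il6 at least 1040-fold and Csf3 at least 695-fold higher (adjusted p = 4.47e-05, 0.000779 and 0.000362). Il1a was at least 284-fold, Csf2 at least 204-fold and Ifnb1 at least 50.3-fold higher (adjusted p = 0.000664, 0.000581 and 0.00229). Tnf stood at 5.14 (SE 0.19, adjusted p = 0.00011), Nos2 at 4.38 (SE 0.17, adjusted p = 0.00011) and Ccl3 at 5.65, while Nfkbiz (4.96), Tnfaip3 (3.89) and Nfkbia (3.22) stayed raised. Hmox1, the haem-degrading enzyme, rose by 0.68 (SE 0.10, adjusted p = 0.0035).

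Trib3 rose by 3.71 (SE 0.10, adjusted p = 6.41e-05), Chac1 by 4.04 (SE 0.16, adjusted p = 0.000125) and Atf4 itself by 1.89 (SE 0.05, adjusted p = 6.21e-05). So did the cystine transporter Slc7a11 (2.59), hexokinase Hk2 (1.66) and the glucose transporter Slc2a1 (1.67). Ranbp3l fell by 6.75 (SE 0.09, adjusted p = 5.73e-06), Klhl30 was at least 30.9-fold lower (adjusted p = 0.000504) and Hpgd at least 20.6-fold (adjusted p = 0.00242). Rnf144b was at least 17.7-fold (adjusted p = 0.00182) and Pik3ip1 at least 8.48-fold lower (adjusted p = 0.000643). Kbtbd11 fell by 5.08 (SE 0.55, adjusted p = 0.00151), Trp53inp1 by 3.96 (SE 0.25, adjusted p = 0.000375, but 0.105 among genes above background on all 8 arrays) and Abcg1 by 3.65 (adjusted p = 0.000338). Of 15 circadian clock genes 6 fell and 4 rose (median -0.04, camera adjusted p = 0.539), with Nr1d2 at -2.30 (adjusted p = 0.000793), Tef at -1.69 (adjusted p = 0.00132), Dbp at -1.50 (adjusted p = 0.00138) and Nfil3 at 1.58 (adjusted p = 0.000668). The calls of Irf7 (0.69, adjusted p = 0.0382) and Il12b (at least 1.43-fold higher, adjusted p = 0.0294) were lost with no filter and with the common floor. Leaving out 2 of the arrays in turn ended that of Irf7, and 5 that of Il12b. Quantile normalization, the deposited table and no intensity trend also ended the call of Irf7. Irf1 stood at -0.38 (adjusted p = 0.686).

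By list at 5 h, 20 of 21 cytokines rose (20 over the list alone; median 5.11, camera adjusted p = 1.94e-08), 12 of 15 chemokines (14; median 6.24, camera adjusted p = 4.67e-08) and 19 of 20 NF-kB feedback genes (median 2.79, camera adjusted p = 8.4e-10), each with adjusted p = 0.475 with an estimated correlation. So did 15 of 20 immediate early genes (15; median 2.47, camera adjusted p = 2.71e-05) and 13 of 16 ATF4 targets (13; median 1.16, camera adjusted p = 6.26e-06), both with adjusted p = 0.475 with an estimated correlation. Of 37 interferon response genes 29 rose (33 over the list alone; median 2.42, camera adjusted p = 9.72e-08, adjusted p = 0.593 with an estimated correlation), among them Gbp3 at 5.13, a GTPase of cell-autonomous defence. Genes of nitric oxide, prostaglandin and antimicrobial products had 12 of 15 raised and 1 lowered (median 2.22, camera adjusted p = 3.15e-05, adjusted p = 0.475 with an estimated correlation). Toll-like receptor signalling had 15 of 24 raised and 2 lowered (15 and 3; median 0.66, camera adjusted p = 0.00262, adjusted p = 0.475 with an estimated correlation). Of 22 G2/M genes 20 fell (21 over the list alone; median -1.33, camera adjusted p = 4.34e-09, adjusted p = 0.552 with an estimated correlation), with Birc5 down by 1.77 and Mki67 by 1.71. Of 21 G1/S genes 19 fell (19 over the list alone; median -1.22, camera adjusted p = 1.46e-08, adjusted p = 0.475 with an estimated correlation). Of 21 genes of cholesterol synthesis 13 rose and 3 fell (camera adjusted p = 0.0117, adjusted p = 0.552 with an estimated correlation). Limma called 8879 genes, 4993 raised and 3886 lowered (56.2% raised), or 3594 and 4638 (43.7% raised) with quantile normalization, and 1404 and 1772 of the 8879 changed at least 2-fold. The count was 4478 without the 0 h array and 5713 without the 5 h array of the arm without melatonin.

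**Figure D1:**
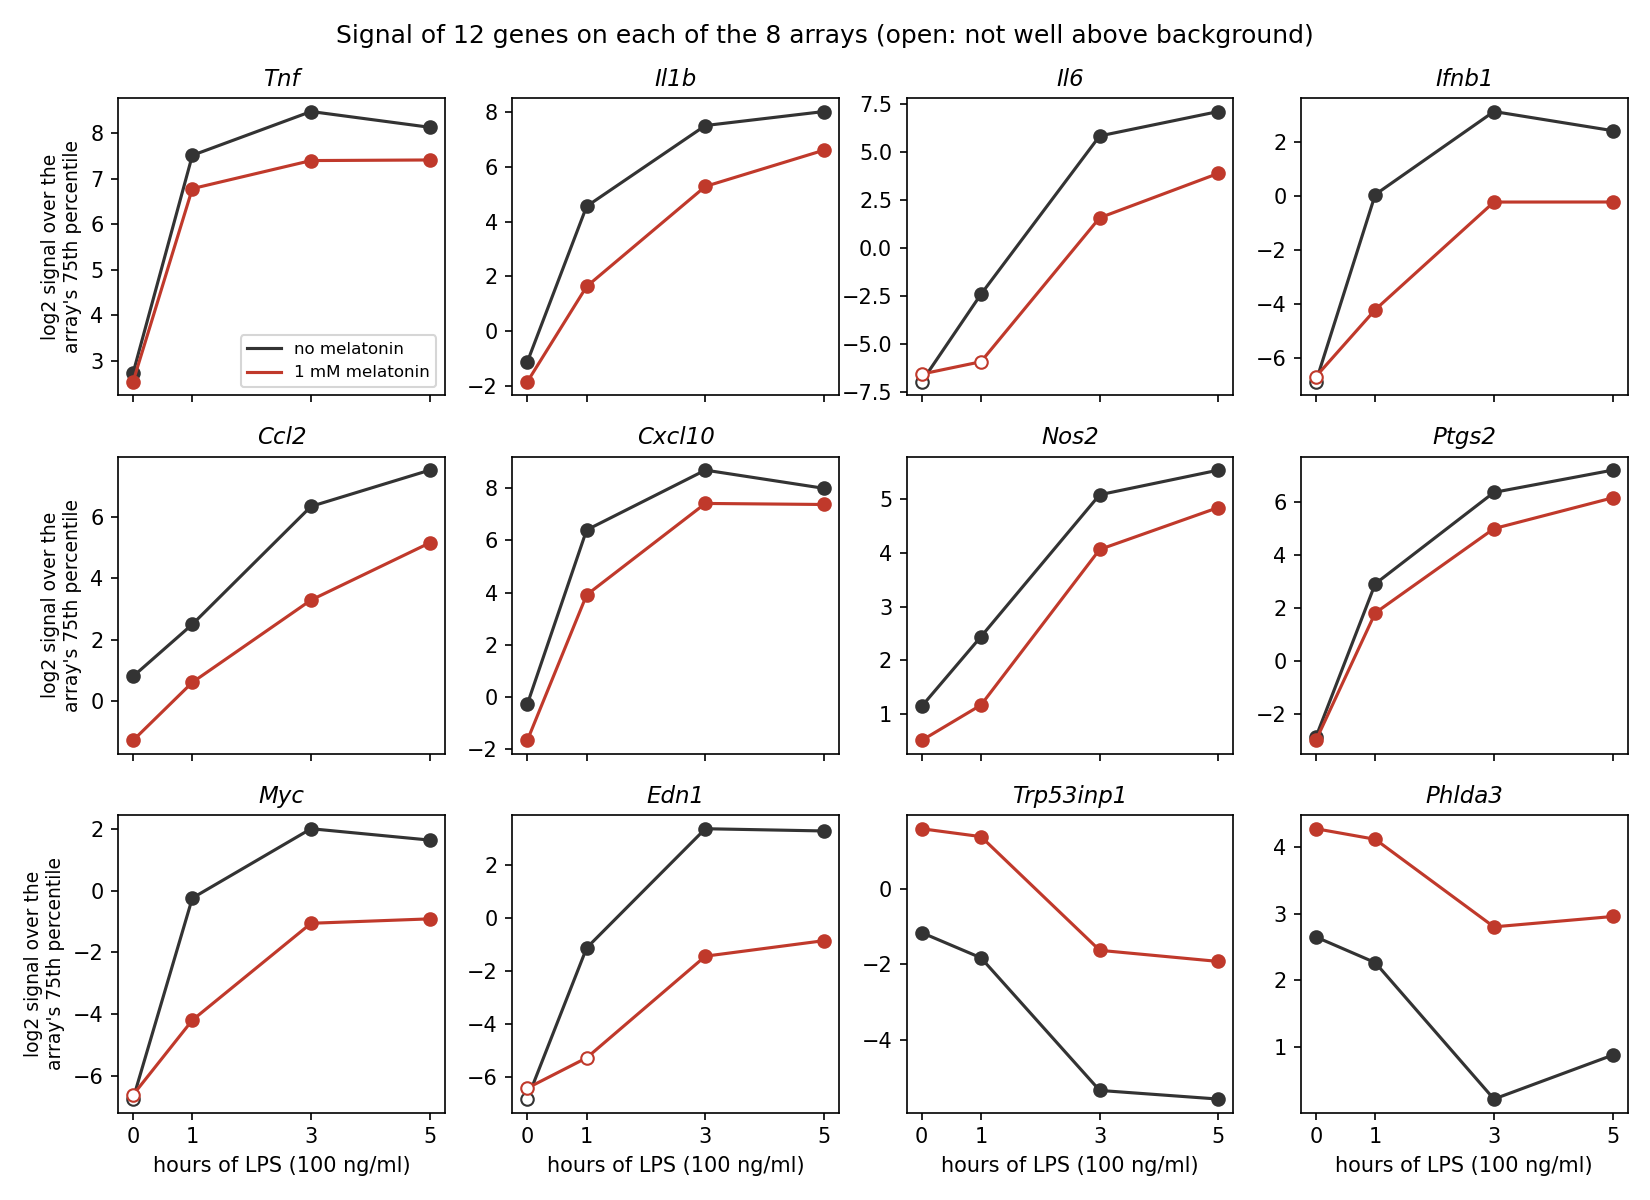
Log2 level (minus the array's 75th percentile) of 12 genes against hours of LPS at 100 ng/ml, without and with 1 mM melatonin, with 1 array per point. Open points mark arrays where no probe of the gene was well above background. Some probe of Trp53inp1 was well above background on every array, but the plotted probe was not, which its filled points do not show. Ccl2 lay lower with melatonin by 2.08, 1.89, 3.04 and 2.36 at 0, 1, 3 and 5 h, and Trp53inp1 lay higher by 2.75, 3.21, 3.71 and 3.65.

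Several lists had no call at the LPS times or moved both ways. NRF2 targets had 2, 4 and 5 of 17 raised and 0, 6 and 5 lowered at 1, 3 and 5 h (4 and 1, 4 and 6, and 5 and 8 over the list alone; camera adjusted p = 0.333, 0.591 and 0.869). Their medians lay below 0 at each time (-0.00, -0.24 and -0.12), with a test direction of up at 1 h. Circadian clock genes had 1, 3 and 4 of 15 raised and 0, 5 and 6 lowered (camera adjusted p = 0.759, 0.292 and 0.539). The chaperones of the unfolded protein response had 0, 4 and 6 of 15 raised, with 1 lowered at 5 h (camera adjusted p = 0.219, 0.481 and 0.0645). Their median at 3 h was 0.10, or -0.06 with quantile normalization. LXR targets had 0, 1 and 2 of 9 raised and 0, 4 and 5 lowered (camera adjusted p = 0.539, 0.103 and 0.0819). The p53 targets had 2, 4 and 4 of 13 raised and 0, 4 and 4 lowered (camera adjusted p = 0.0479, 0.912 and 0.925). They had a median of 0.36 and a mean of -0.19 at 3 h, and 0.40 and -0.15 at 5 h. The call of p53 targets at 1 h had adjusted p = 0.552 with an estimated correlation, 0.0529 with normexp and 0.0771 with quantile normalization. The cAMP/CREB targets had 1 of 9 raised at 1 h (4 over the list alone, camera adjusted p = 0.00187, adjusted p = 0.502 with an estimated correlation) and camera adjusted p = 0.896 and 0.912 later. Heat shock genes had 1, 6 and 7 of 10 raised and 0, 1 and 1 lowered (camera adjusted p = 0.00187, 0.126 and 0.0656, and for the 1 h call adjusted p = 0.475 with an estimated correlation). Quantile normalization left 2 raised and 1 lowered at 3 h and at 5 h. Dnaja1 stood at 0.44 at 3 h and -0.07 as the mean over its probes, and quantile normalization also ended its call.

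Genes of hypoxia and glycolysis had 3, 12 and 14 of 22 raised and 0, 4 and 4 lowered (3 and 0, 13 and 5, and 15 and 4 over the list alone; camera adjusted p = 0.00105, 0.0343 and 0.0125). These had adjusted p = 0.53, 0.616 and 0.588 with an estimated correlation and 0.51 and 0.284 at 3 and 5 h with quantile normalization, which left 6 raised and 6 lowered at 3 h and 8 and 6 at 5 h, and 0.0966 and 0.061 with normexp. G2/M genes at 1 h had camera adjusted p = 0.0656 and G1/S genes 0.036, the latter with adjusted p = 0.673 with an estimated correlation. ATF4 targets at 1 h had camera adjusted p = 0.261 and cholesterol synthesis at 3 h 0.55. Ribosomal protein genes had 0, 16 and 18 of 20 raised at 1, 3 and 5 h (0, 17 and 19 over the list alone; medians 0.03, 0.17 and 0.23, camera adjusted p = 0.0308, 2.93e-05 and 4.98e-06, with adjusted p = 0.705, 0.558 and 0.552 with an estimated correlation). Quantile normalization left medians of 0.00, 0.01 and 0.01 with 0, 0 and 0 raised and 0, 0 and 3 lowered (camera adjusted p = 0.477, 0.909 and 0.909). Housekeeping genes had medians of 0.01, 0.14 and 0.22, or -0.00, -0.01 and -0.03 with quantile normalization (camera adjusted p = 0.971, 0.821 and 0.839).

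Markers of other cell types moved with LPS in this single line. The dendritic cell factor Zbtb46, well above background on 1 of 2 arrays without LPS, rose at 1, 3 and 5 h, and 3 of 5 measured dendritic markers rose at 3 h and at 5 h, with Ccr7 and Itgax the others. Camera gave adjusted p = 0.0224, 0.0125 and 0.0278 at the 3 times (adjusted p = 0.475 with an estimated correlation, 0.098 at 1 h with normexp and 0.0512 at 5 h with quantile normalization). Among 4 measured T cell markers Cd3d (1.53 and 1.52) and Lck (0.87 and 1.39) rose at 3 and 5 h. Among 4 B cell markers Cd79b was at least 3.14-fold and 5.03-fold higher and Blnk rose by 0.80 at 5 h. Col1a2, the only fibroblast marker measured of 8 and well above background on 1 of 2 arrays without LPS, rose at 3 h. None of 6 epithelial markers passed the filter. Macrophage identity genes had 0, 4 and 5 of 16 raised and 0, 5 and 5 lowered (camera adjusted p = 0.631, 0.472 and 0.653). Csf1r, the receptor of the macrophage growth factor, fell by 1.46 and the scavenger receptor Msr1 rose by 1.88 at 5 h. Osteoclast markers had 0, 2 and 1 of 7 raised and 0, 1 and 2 lowered (camera adjusted p = 0.519, 0.759 and 0.908), with Nfatc1, the master factor of osteoclasts, down by 2.49 at 3 h. IL-4 type genes had 1, 2 and 1 of 6 raised and 0, 1 and 1 lowered (camera adjusted p = 0.365, 0.261 and 0.698). Among 4 measured AHR targets Tiparp rose by 1.61 and 1.37 at 3 and 5 h, while Ahrr fell at 3 h (1 of 2 arrays well above background) and was at least 2.13-fold lower at 5 h. Of 4 measured genes of melatonin reception and synthesis 0, 0 and 2 fell, Rora and Nqo2, and both melatonin receptors, Mtnr1a and Mtnr1b, were below the filter. Leaving out the 3 h array without melatonin ended the 3 h calls of Lck, Cd79b, Col1a2, Ahrr and Ccr7, with adjusted p up to 0.159, 0.086, 0.14, 0.0936 and 0.152 when an array was left out. The 1 h call of Zbtb46 ended without the 1 h array of that arm (0.0513), and the 5 h calls of Rora and Nqo2 ended with other arrays left out (up to 0.206 and 0.0944). The common floor ended the calls of Cd79b at 3 and 5 h (0.303 and 0.163) and that of Zbtb46 at 1 h (0.0661).

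In the fit over the 4 times, p53-linked genes lay higher with melatonin and chemokines, cytokines and proliferation genes lower, though not each of these lists at each time. Trp53inp1, a p53-induced regulator of cell death and autophagy, rose by 3.33 log2 (SE 0.18, adjusted p = 0.00222) and Phlda3, a p53 target that restrains AKT, by 2.04 (SE 0.16, adjusted p = 0.00227). Ccl2 fell by 2.34 (SE 0.19, adjusted p = 0.00227) and Cxcl10 by 1.44 (SE 0.28, adjusted p = 0.0124). Ccl9 fell by 1.26 (SE 0.09, adjusted p = 0.00222) and Nos2 by 0.91 (SE 0.12, adjusted p = 0.00462). These 4 lay lower with melatonin at all 4 times. Il1rn, the antagonist of the interleukin-1 receptor, fell by 2.60 (SE 0.32, adjusted p = 0.00427). The calls of these 7 genes held under every alternative that tested them.

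Other rises with melatonin were Hid1 (at least 4.73-fold, adjusted p = 0.00226) and Serinc5, a restriction factor of retroviruses (at least 3.36-fold, adjusted p = 0.00352). Tmem220 (adjusted p = 0.00485) and Inka2 (adjusted p = 0.00264) also rose, but only 2 and 1 of the 4 arrays without melatonin were well above background, so the size is not measured. Asb4 (at least 3.44-fold), Serpini1 (2.07-fold), Abhd3 (1.77-fold), Ttll9 (1.32-fold) and Gria2 (1.15-fold) had adjusted p = 0.00963, 0.00333, 0.00307, 0.012 and 0.00909. The common floor ended the calls of Inka2 and these 5, and leaving out the 3 h melatonin array those of Ttll9 and Gria2 (adjusted p = 0.0558 and 0.0524). Leaving out that array removed the 3 h pair from the melatonin difference, as leaving out the other 3 h array also does. Uggt2 (adjusted p = 0.0291) and Igsf3 (adjusted p = 0.032), each well above background on 1 array without melatonin, lost the call under several alternatives, with adjusted p up to 0.178 and 0.0987.

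Falls that held under every alternative were Cd5, a scavenger receptor family member (-2.44, SE 0.16, adjusted p = 0.00222), Bcl6b, a transcriptional repressor (-2.33, SE 0.11, adjusted p = 0.00222), and Mtmr7, a lipid phosphatase (-2.32, SE 0.11, adjusted p = 0.00222). Tnc, a matrix protein (-2.67, adjusted p = 0.00781), Il1f6, an interleukin-1 family cytokine (at least 2.48-fold lower, adjusted p = 0.00677), and Serpinb10 (at least 1.88-fold lower, adjusted p = 0.00366) lost the call with the common floor alone. Rgs1, which shortens G protein signals, fell by 2.77 (adjusted p = 0.019), Cd300e by 2.33 (adjusted p = 0.0177) and Saa3 by 2.32 (adjusted p = 0.014), and Lrrc32 was at least 3.18-fold lower (adjusted p = 0.0216). Leaving out either 5 h array ended the calls of these 4, and either 3 h array those of Rgs1 and Lrrc32, with adjusted p up to 0.0784, 0.0669, 0.0547 and 0.0853; the common floor and no filter also ended that of Lrrc32.

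**Figure D2:**
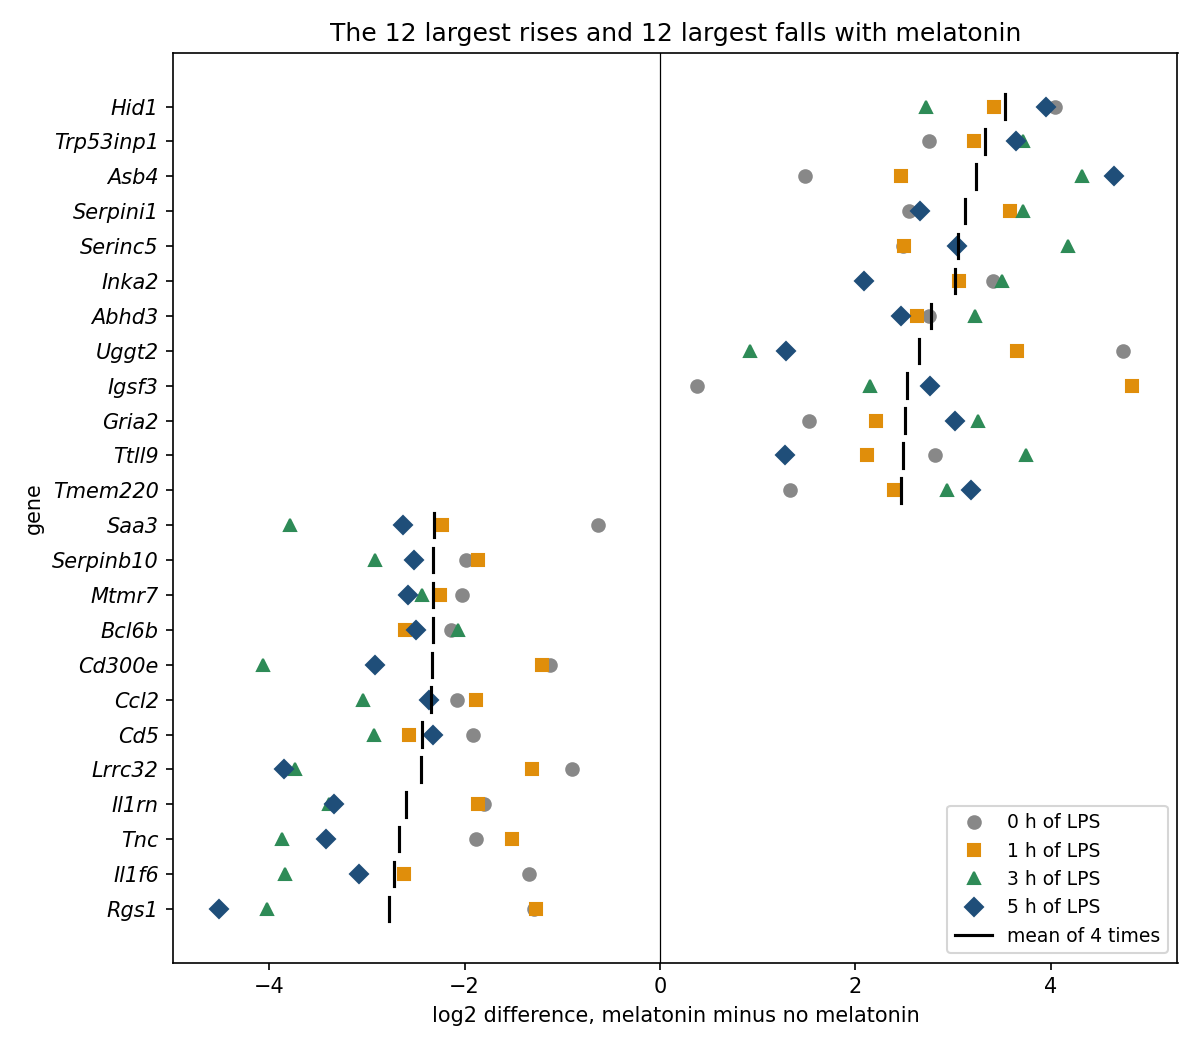
Log2 difference, melatonin minus no melatonin, of 24 genes at 0, 1, 3 and 5 h of LPS (1 marker per time) with their mean. These are the 12 largest fitted rises and the 12 largest fitted falls among called genes with the same sign at all 4 times. The shared sign is thus a condition of the choice, and larger falls without it, such as Edn1 (-3.16), are left out. Some of the genes were not well above background on every array. Those with some probe of the gene well above background on each of the 8 arrays run from Trp53inp1 (mean 3.33) to Rgs1 (mean -2.77). The plotted probe of Trp53inp1 itself was not well above background on all 8.

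Of 21 cytokines 13 fell and 0 rose with melatonin (14 fell over the list alone; median -0.95, camera adjusted p = 0.00208, adjusted p = 0.593 with an estimated correlation). Il1b fell by 1.82 (SE 0.35, adjusted p = 0.0117) and Tnf by 0.68 (SE 0.14, adjusted p = 0.0132). Tnf lost the call without the 1 h or 5 h array of the arm without melatonin or the 5 h array with it (adjusted p up to 0.0504), and Il1b without either 3 h array (adjusted p up to 0.0565). Leaving out either array of a time removes the same pair from the melatonin difference. That Tnf lost the call with only 1 array of the 1 h pair left out thus reflects an adjusted p near the threshold, not a role of that array. Il6 (-2.64, SE 0.74, adjusted p = 0.0362), Ifnb1 (-2.52, adjusted p = 0.0337), Csf2 (-2.22, adjusted p = 0.0214) and Il1a (-1.997, adjusted p = 0.0434) passed the test over the 4 times. So did the vasoconstrictor Edn1 (-3.16, adjusted p = 0.033) and the transcription factor Myc (-2.36, adjusted p = 0.0317). Leaving out any of the 6 LPS arrays ended these 6 calls, with adjusted p up to 0.13, 0.125, 0.0837, 0.151, 0.123 and 0.118. It ended as well those of Ptgs2 (-0.91, adjusted p = 0.0178) and Tnfaip3 (-1.23, adjusted p = 0.018), with up to 0.0714 and 0.0724. The common floor and no filter also ended the calls of Il6, Ifnb1, Csf2, Il1a, Edn1 and Myc. Without LPS, Il6, Ifnb1, Il1a, Edn1 and Myc did not lie lower with melatonin. With Osgin1 and Sesn2 they were the exceptions among 128 named calls, of which 121 kept their sign at all 4 times. For the 12 largest rises and 12 largest falls the naming rule required this, so that part of the count was fixed in advance. The other calls were chosen by a test over the same 4 differences, which favours a shared sign.

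Of 15 chemokines 10 fell (10 over the list alone; median -1.21, camera adjusted p = 0.000458, adjusted p = 0.475 with an estimated correlation), with Cxcl2 at -1.64 (adjusted p = 0.00394, a call lost with the common floor). Ccl3 (-0.72, adjusted p = 0.0354) and Ccl5 (-0.28, adjusted p = 0.0303) lost theirs under several settings, quantile normalization included. Genes of nitric oxide, prostaglandin and antimicrobial products had 10 of 15 lowered (11 over the list alone; median -0.56, camera adjusted p = 0.00642, adjusted p = 0.552 with an estimated correlation). Of 20 NF-kB feedback genes 8 fell (8 over the list alone; median -0.38, camera adjusted p = 0.0308, adjusted p = 0.668 with an estimated correlation, 0.0529 with normexp and 0.0619 with quantile normalization). Nfkb1 fell by 0.65, Bcl3 by 0.70 and Nfkbia by 0.31, the last call lost with quantile normalization, and Nfkbiz stood at -0.53 (adjusted p = 0.218). Of 37 interferon response genes 6 fell (0 over the list alone; median -0.57, camera adjusted p = 0.0308, adjusted p = 0.804 with an estimated correlation). With the common floor 6 cytokines, 6 chemokines and 1 interferon response gene fell. Of 20 immediate early genes 1 rose and 4 fell (0 and 2 over the list alone, camera adjusted p = 0.724). Of 24 Toll-like receptor signalling genes 3 rose and 9 fell (3 and 10, camera adjusted p = 0.164), with the RNA sensor Tlr7 at -0.94. In the panel, Hmox1 stood at -0.12 (adjusted p = 0.199; 0.06 with quantile normalization), Irf1 at 0.26 (adjusted p = 0.691), Irf7 at -0.38 (adjusted p = 0.0815) and Il12b had adjusted p = 0.111.

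Of 13 p53 targets 8 rose and 1 fell (9 and 1 over the list alone; median 0.53, camera adjusted p = 6.62e-05, adjusted p = 0.475 with an estimated correlation). The death receptor Eda2r rose by 1.19 (SE 0.13, adjusted p = 0.00362) and Pmaip1, a pro-apoptotic BCL-2 family member, by 0.92 (SE 0.08, adjusted p = 0.00265). Of 17 NRF2 targets 9 rose and 2 fell (9 and 2; median 0.28, camera adjusted p = 0.0278, adjusted p = 0.502 with an estimated correlation). The antioxidant enzyme Srxn1 rose by 1.81 (adjusted p = 0.0101), Gclm of glutathione synthesis by 0.62 (adjusted p = 0.0063) and catalase, Cat, by 0.61 (adjusted p = 0.0161, and up to 0.0541 without either 1 h array). Of 16 ATF4 targets 6 rose and 1 fell (9 and 2; median 0.28, camera adjusted p = 0.0092, adjusted p = 0.475 with an estimated correlation). These counts moved to 12 and 0 with quantile normalization and to 2 and 1 with the common floor. Ddit4, an inhibitor of mTOR complex 1, rose by 1.56 (adjusted p = 0.005) and Trib3 by 0.74.

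Of 22 G2/M genes 17 fell and 0 rose with melatonin (18 fell over the list alone; median -0.59, camera adjusted p = 9.21e-05, adjusted p = 0.623 with an estimated correlation). The calls of the mitotic kinases Plk1 (-0.91) and Cdk1 (-0.84) ended without either 3 h array (adjusted p up to 0.0507 and 0.0604). Of 21 G1/S genes 9 fell (9; median -0.33, camera adjusted p = 0.0125, adjusted p = 0.618 with an estimated correlation), with thymidylate synthase, Tyms, at -0.73. With quantile normalization 11 G2/M and 5 G1/S genes fell. Of 21 genes of cholesterol synthesis 17 fell and 1 rose (17 and 2; median -0.46, camera adjusted p = 0.000536, adjusted p = 0.475 with an estimated correlation). Hmgcs1 of the mevalonate pathway stood at -1.04 (SE 0.16, adjusted p = 0.00679) and Srebf2, an activator of the pathway, at -0.64. Of 22 genes of hypoxia and glycolysis 16 fell and 1 rose (16 and 1; median -0.29, camera adjusted p = 0.000347, adjusted p = 0.502 with an estimated correlation), with Hk2 at -0.78 and Ndrg1 at -0.92. Of 16 macrophage identity genes 11 fell and 1 rose (13 and 1; median -0.42, camera adjusted p = 0.00109, adjusted p = 0.475 with an estimated correlation). Among them were the pore-forming protein Mpeg1 (-1.14, adjusted p = 0.00564), Msr1 (-1.07, adjusted p = 0.00227) and the antibody receptor Fcgr1 (-0.98, adjusted p = 0.00802).

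Ribosomal protein genes had 17 of 20 lowered (19 over the list alone; median -0.17, camera adjusted p = 1.52e-05, adjusted p = 0.552 with an estimated correlation), but 7 raised, 0 lowered, a median of 0.01 and camera adjusted p = 0.149 with quantile normalization. Housekeeping genes had 7 of 10 lowered (8; median -0.30, camera adjusted p = 0.00399, adjusted p = 0.475 with an estimated correlation), and 4 lowered with camera adjusted p = 0.059 with quantile normalization. Heat shock genes had 2 of 10 raised and 3 lowered (camera adjusted p = 0.971), with a median of -0.12, a mean of 0.15 and a median of 0.09 with quantile normalization, and Hspa1b at 1.40. LXR targets had 1 of 9 raised and 2 lowered (camera adjusted p = 0.821), with a median of -0.09, a mean of 0.09 and a median of 0.05 with quantile normalization. Abcg1, which LPS lowered, rose by 1.28 (SE 0.15, adjusted p = 0.00391). Of 15 circadian clock genes 2 rose, Tef and Nr1d2 (1.13 and 0.90), and 4 fell, with the repressor Cry1 at -0.79 (camera adjusted p = 0.384). The chaperones of the unfolded protein response had 1 of 15 raised and 6 lowered (1 and 7; camera adjusted p = 0.203), or 2 and 1 with quantile normalization. The cAMP/CREB targets had 3 of 9 raised and 2 lowered (3 and 3; camera adjusted p = 0.971), with a median of -0.47 but a test direction of up. Of the melatonin receptor and synthesis list Rora rose (adjusted p = 0.00742, lost with normexp and with the common floor; 1 array without melatonin well above background) and Aanat, the rate-limiting enzyme of melatonin synthesis, fell by 0.47. None of the 4 AHR targets was called by limma, over all genes or over the list alone.

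Markers of other cell types also moved with melatonin. All 4 measured T cell markers lay lower, with Cd3e at -0.36 (adjusted p = 0.00907), Cd4 at -0.35 (adjusted p = 0.00808, but 0.589 as the mean over its probes), and Lck at -0.49 and Cd3d at -0.47. The calls of Lck and Cd3d ended with quantile normalization and with any of the 6 LPS arrays left out (adjusted p up to 0.139 and 0.149). Of 4 B cell markers 2 fell, Cd79b (1 array with melatonin well above background, adjusted p = 0.0254, up to 0.0973 with 1 LPS array left out) and Blnk (-0.55, adjusted p = 0.00379). Dendritic markers had 2 of 5 lowered, Itgax and Zbtb46 (camera adjusted p = 0.205). The call of Zbtb46 (adjusted p = 0.0326) ended with any of the 6 LPS arrays left out (up to 0.12), with no filter and with the common floor. The common floor and no filter also ended that of Cd79b. Osteoclast markers had 2 of 7 lowered (3 over the list alone, camera adjusted p = 0.868). IL-4 type genes had 1 of 6 raised and 1 lowered (2 and 2, camera adjusted p = 0.591). Col1a2 stood at -0.68, lowered only when adjusted over the list alone.

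Limma called 8158 genes for melatonin, 3079 raised and 5079 lowered (37.7% raised), or 3782 and 3452 (52.3% raised) with quantile normalization, with 6437 calls shared by both. In all, 10426 genes had an unadjusted p under 0.05 where chance gives 1004. At least 2-fold differences were found for 476 raised and 343 lowered genes, 121 and 144 with normexp, 241 and 175 among genes above background on all 8 arrays, and 263 and 161 with the common floor. The count of calls was 4130 and 4142 without the 1 h arrays without and with melatonin, and 4220 and 4213 without those of 3 h. Either array of a time removes the same pair, so the 2 counts of a time are not separate checks. All melatonin arrays occupied 1 slide row and all others the other row, so melatonin and slide row cannot be told apart here.

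At single times the differences are values without a test, ranked here among genes well above background on both arrays. Without LPS the largest were Robo3 (2.83), Trp53inp1 (2.75), Plk2 (2.70) and Dnajc28 (2.57) on the higher side with melatonin, and Plau (-2.50), Ccr6 (-2.40), Bcl6b (-2.14) and Slc17a6 (-2.10) on the lower. At 1 h they were Trp53inp1 (3.21), Inka2 (3.06), Csrnp2 (2.93) and Robo3 (2.90), and Ifnb1 (-4.26), Myc (-3.96), Il4i1 (-3.05) and Il1b (-2.93). At 3 h they were Zfp438 (3.69), Tob1 (2.98), Srxn1 (2.90) and Rhod (2.87), and Edn1 (-4.80), Il6 (-4.25), Ccl17 (-4.12) and Cd300e (-4.06). At 5 h they were Rhod (3.27), Tmem37 (2.80), Dusp28 (2.75) and Aph1c (2.73), and Rgs1 (-4.51), Edn1 (-4.13), Lta (-3.78) and Rgs2 (-3.76). The 3 and 5 h rankings leave out Trp53inp1, whose differences at both times were larger than those listed on the higher side. Some probe of Trp53inp1 was well above background on every array, but the probe plotted for it was not. Genes at least 2-fold higher and lower with melatonin, among those well above background on both arrays, numbered 246 and 183 of 17903 without LPS and 418 and 294 of 17996 at 1 h. They numbered 753 and 690 of 17719 at 3 h, and 693 and 504 of 17011 at 5 h.

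Interferon response genes lay lower with melatonin at 3 and 5 h of LPS, with 37 and 33 of 37 members lower and median differences of -1.87 and -0.77. Without LPS and at 1 h the medians were 0.16 and 0.05, with 10 and 17 members lower. Each value compares 1 array with 1, and the genes of this list move together (estimated correlation 0.82), so its members are not separate evidence. At 3 h Rsad2 lay at -2.39 and Ifit1 at -2.83, and at 5 h Rsad2 lay at -0.06. Cytokines had medians of -0.19, -0.94, -1.71 and -1.21 at 0, 1, 3 and 5 h, and chemokines -0.75, -1.49, -1.39 and -0.92. The median of p53 targets was 0.89, 0.72, 0.53 and 0.42, that of G2/M genes -0.30, -0.30, -0.74 and -1.07, and that of G1/S genes -0.55, -0.54, -0.24 and 0.01.

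**Figure D3:**
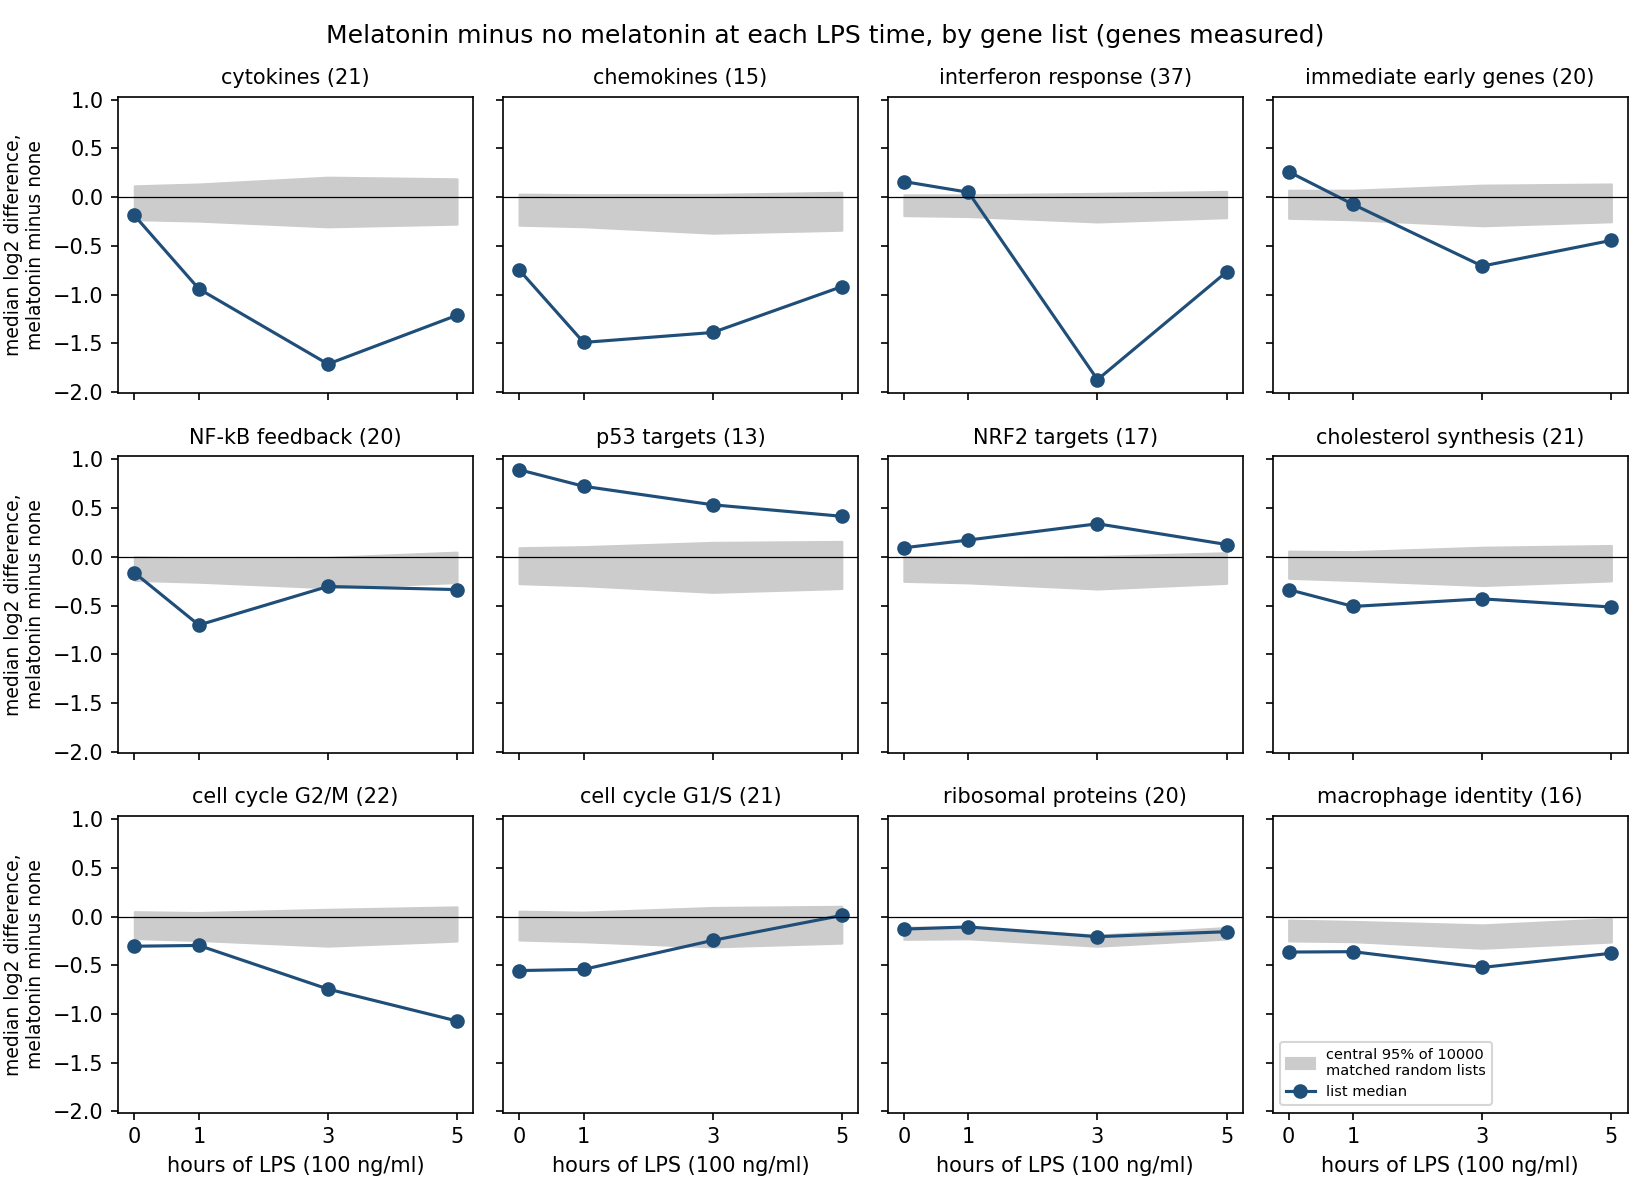
Median log2 difference, melatonin minus no melatonin, of 12 gene lists (genes measured in parentheses) at 0, 1, 3 and 5 h of LPS, with the central 95% of 10000 random lists matched on mean level in grey. Interferon response genes go from 0.16 without LPS to -1.87 at 3 h, and p53 targets stay above the random lists at each time.

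On whether melatonin acts differently under LPS, several genes of the cytokine, interferon response and immediate early lists had values well below 0. The melatonin by LPS term of Il6 was -4.06 log2, of Edn1 -4.77, of Ifnb1 -3.61, of Myc -3.33 and of Il1a -3.18. These genes, and Csf2 and Csf3, were not well above background without LPS in either arm, so their terms rest on 0 h values near background and their size is not measured. Adjusted over the list alone, uncorrected between lists, 8 of 21 cytokines and 7 of 20 immediate early genes passed with a lower difference. So did 3 of 20 NF-kB feedback genes and 3 of 15 chemokines, each with the difference lower under LPS than without. Among them were Edn1 (adjusted p = 0.00052), Il6 (0.00161), Csf2 (-2.81, 0.00236), Nfkbiz (-1.72, 0.00256), Il1a (0.00481) and Csf3 (-2.65, 0.00481). Others were Fosl1, a partner of JUN (-1.58, 0.0072), Tnfaip3 (-1.44, 0.0102) and Tnf (-0.66, 0.0345), and, in the list of nitric oxide, prostaglandin and antimicrobial products, Ptgs2 (-1.04, 0.0286). The term sets 3 pairs of arrays under LPS against 1 pair without LPS, whose own spread is not measured, so these counts depend on that pair. With no later pair without LPS, the term cannot tell LPS apart from the hours elapsed since melatonin was added. Klf4 had the opposite sign (1.90, 0.0487 over the list alone). Of 37 interferon response genes, Ifnb1 among them, 0 passed over the list alone.

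Over all genes, limma called 0 of 20076 for this term, with 754 at an unadjusted p under 0.05 where chance gives 1004, and a smallest adjusted p of 0.459. The fit with melatonin by hours of LPS as a slope also called 0, but had 3768 at an unadjusted p under 0.05. Without the 1 h arrays with and without melatonin, 40 and 17 genes were called and 2700 and 2684 had an unadjusted p under 0.05. The largest values by the fixed rule were Fcgbp (5.59, SE 1.34), Unc80 (-5.02), Myh2 (4.81, SE 1.01), Nkx1-2 (4.80, SE 1.65) and Edn1 (SE 0.34), the earlier 4 well above background on only 2 or 3 arrays. The other panel values were Il1b -1.46, Cxcl2 -0.90, Irf7 -0.47, Nos2 -0.36, Ccl5 -0.36, Irf1 -0.36 and Ccl2 -0.35. They were Nfkbia -0.17, Cxcl10 -0.07 (0.11 with quantile normalization), Ccl3 0.04, Hmox1 0.07 and Il12b 0.23. Cxcl2 and Il12b were not well above background without LPS in either arm, so the size of their terms is not measured. Lists not called for this term were Toll-like receptor signalling (camera adjusted p = 0.0819), NRF2 targets (0.0985, but 0.0357 with normexp and 0.0335 with quantile normalization), circadian clock (0.0591), ATF4 targets (0.203), heat shock (0.896) and cholesterol synthesis (0.0562). Nor were LXR targets (0.766), IL-4 type genes (0.475), macrophage identity (0.264, median -0.06 and mean 0.01), osteoclast markers (0.326), ribosomal proteins (0.289) and housekeeping genes (0.653).

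The median LPS response of the genes that LPS raised was smaller with melatonin at each time. All 3 times subtract the same 2 arrays without LPS, 1 per arm, so they are not 3 separate results. Of the 336 genes raised at 1 h, 249 (74.1%) responded less with melatonin. The median response went from 1.69 to 1.45 log2, with a median difference of -0.23 against -0.01 to 0.02 in matched random lists. Such ranges come from the draw of genes and hold neither the spread between arrays nor the shared movement of LPS genes. At 3 h it was 2689 of 3735 genes (72%), with a median difference of -0.12 (random lists -0.03 to -0.01), and at 5 h 3144 of 4993 (63%), with -0.07 (random lists 0.01 to 0.03). Genes that LPS lowered fell less with melatonin, with median differences of 0.13, 0.25 and 0.29 for the 57, 3031 and 3886 genes lowered at 1, 3 and 5 h. Tnf went from 2.73 to 8.48 log2 between 0 and 3 h without melatonin and from 2.54 to 7.40 with it, and Il1b from -1.14 to 7.51 without and from -1.87 to 5.29 with it.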

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

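The tests of the lowered genes, the slide row, the signal floor and the signal range were chosen only after the results they bear on had been seen, and so was the test of the raised genes, though before its own result.

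The term that compares the melatonin difference under LPS with that without LPS was called by camera for 13 lists at the preset correlation, and for 0 with an estimated one. The median term was -1.066 for cytokines (21 measured, camera adjusted p = 6.62e-14, adjusted p = 0.475 with an estimated correlation). For interferon response genes it was -0.892 (37 measured, camera adjusted p = 3.09e-10, adjusted p = 0.588 with an estimated correlation), with 0 of 37 passing when adjusted over the list alone. Immediate early genes had -0.607 (camera adjusted p = 2.47e-08, adjusted p = 0.475 with an estimated correlation). Chemokines had -0.36 (camera adjusted p = 2.53e-06, adjusted p = 0.475 with an estimated correlation). G2/M genes had -0.421 (camera adjusted p = 6.26e-06, adjusted p = 0.616 with an estimated correlation). Genes of nitric oxide, prostaglandin and antimicrobial products had -0.456 (camera adjusted p = 2.71e-05, adjusted p = 0.475 with an estimated correlation), with 1 of 15 lowered when adjusted over the list alone. NF-kB feedback genes had -0.279 (camera adjusted p = 6.62e-05, adjusted p = 0.518 with an estimated correlation). The p53 targets had -0.319 (camera adjusted p = 0.0119, adjusted p = 0.475 with an estimated correlation), with 1 of 13 lowered when adjusted over the list alone.

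G1/S genes had 0.231, a smaller deficit with melatonin under LPS than without (camera adjusted p = 0.0122, adjusted p = 0.664 with an estimated correlation). Genes of hypoxia and glycolysis had -0.073 (camera adjusted p = 0.0168, adjusted p = 0.618 with an estimated correlation). Dendritic markers had -0.354 (5 measured, camera adjusted p = 0.0271, adjusted p = 0.518 with an estimated correlation). The cAMP/CREB targets had -0.396 (9 measured, camera adjusted p = 0.0278, adjusted p = 0.593 with an estimated correlation). Chaperones of the unfolded protein response had 0.167 (camera adjusted p = 0.0308, adjusted p = 0.7 with an estimated correlation).

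The melatonin difference was broad, with 8158 genes called. An additive background of the slide row that holds the melatonin arrays does not account for all of it. The gap in lowest signal (1.45 to 2.22) was added to the other row. Of the 476 raised genes at least 2-fold higher, 88.9% then stayed so. Of the genes at least 2-fold different, 41.9% were lowered. The brightest tercile held 10.9% of them (89 of 819, interval 8.92 to 13.2), above a bound of 10 by less than its spread. The dimmest tercile held 57.4% (470) and the middle 31.7% (260). Large differences thus lay mostly in dim genes, as a background would also give, so the share by brightness does not count against it. Normexp left 121 raised and 144 lowered genes at least 2-fold different, against 476 and 343. A part of background among dim genes stays open. Of the 8 splits that exchange arms within times, 1, the real one, called as many genes, the highest of the others called 0, and 8 splits are too few for a share under 0.05. The differences at the 4 times, which share no array, correlated across genes at r = 0.416 or above, as a slide row effect and a melatonin effect would both give. Melatonin, which the design names, and the slide row cannot be told apart, and either may account for the pattern.

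The response of LPS-raised genes was smaller with melatonin. A higher signal floor on the melatonin row would shrink the responses of dim genes, but among genes above background on all 8 arrays the median difference was -0.245, -0.113 and -0.061 at 1, 3 and 5 h, with intervals below 0 at each time (nearest 0 at 5 h, -0.07 to -0.053). A narrower signal range on the melatonin arrays is countered by -0.208, -0.111 and -0.102 with the same distribution given to every array. A later course with melatonin would have 1 h genes on the decline at 5 h lie higher with melatonin, and 32 such genes had a median response difference of -0.326 (interval -0.466 to -0.053, 11 of 32 higher), although at 1 h they did not respond less (0.076). These 32 genes thus lack the smaller 1 h response that a later course would explain, so they cannot decide that question. A smaller response to LPS under melatonin may remain as a hypothesis, with the slide row open here too, and since all 3 times share 1 pair of 0 h arrays and the intervals resample genes only, -0.245, -0.113 and -0.061 are not 3 separate results.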

How the results depend on the processing

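The tests with a common signal floor were chosen only after the result was seen, as was the limit of the 2-fold counts between arms to genes well above background on both arrays. Of 412 named calls, 248 held under every alternative and 2 reversed, both of Dnaja1, whose probes differ in sign: it had -0.069 at 3 h and -0.039 at 5 h of LPS as the mean over its probes. By comparison, 15 of 48 named calls held at 1 h, 80 of 115 at 3 h, 96 of 121 at 5 h and 57 of 128 for melatonin. Leaving out an array ended 33, 33, 19 and 53 of them, and the common floor 31, 12, 9 and 42. Dim genes limit these data: folds against a group with no array well above background are bounds, those with only some such arrays are of uncertain size, and the cause was not tested for the changes below unless given.

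The 1 h count was 137 with no filter, where more genes share the correction, 98 with the common floor and 159 with no intensity trend. A 2-fold threshold, which keeps fewer genes by construction, left 2380 at 3 h, 3176 at 5 h and 819 for melatonin. With an array left out, and so fewer degrees of freedom, the counts ran from 95 to 320 at 1 h, 2489 to 6816 at 3 h, 4478 to 8375 at 5 h, 4130 to 6769 for melatonin and 0 to 40 for melatonin by LPS. Genes at least 2-fold different at 0, 1, 3 and 5 h numbered 182, 338, 864 and 669 with normexp, and 3199, 4103, 5053 and 4574 with no filter, which adds dim genes. The median response difference of LPS-raised genes was -0.323 at 1 h with no filter and -0.337 at 2-fold, -0.093 at 3 h with the common floor and -0.423 at 2-fold. At 5 h it was -0.102 with quantile normalization, -0.1 with the deposited table, -0.051 with the common floor and -0.33 at 2-fold. Camera with an estimated correlation called 0 lists; quantile normalization shared 59 of the 69 list calls and normexp 63.

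Some values that no test called changed sign. Hmox1 with melatonin was 0.058 with quantile normalization and 0.057 with the deposited table. For melatonin by LPS, Cxcl10 was 0.106 and 0.096 with these, and Il12b -0.006 with the common floor. With an array left out, ranges were -0.295 to 0.18 for Irf7 at 1 h of LPS, -0.732 to 1.926 for Irf1 at 3 h, -0.816 to 0.049 for Irf1 at 5 h and -0.1 to 0.922 for Irf1 with melatonin, and for melatonin by LPS -0.2 to 0.428 for Ccl3, -0.495 to 0.441 for Cxcl10, -0.028 to 0.139 for Hmox1, -0.03 to 0.464 for Il12b and -0.943 to 0.59 for Irf1. The cause was not tested.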

Other observations

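The comparison of LPS with melatonin directions below was chosen only after the results were seen, and no tests were made of it.

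Some named genes moved against each other with melatonin and LPS. Trp53inp1, Phlda3, Abcg1, Tef and Nr1d2 fell with LPS by 3.96, 1.55, 3.65, 1.69 and 2.30 log2 at 5 h, and rose with melatonin by 3.33, 2.04, 1.28, 1.13 and 0.90. Hspa1b, the inducible chaperone of heat shock, fell by 1.58 at 5 h of LPS, a call that ended without the melatonin array at 0 h (adjusted p = 0.0504), and rose by 1.40 with melatonin. Other genes moved the same way with both: Trib3 rose by 3.71 with LPS at 5 h and by 0.74 with melatonin, and of 22 G2/M genes 20 fell with LPS at 5 h and 17 with melatonin, and of 21 G1/S genes 19 and 9. Whether these overlaps exceed chance was not tested.

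Differences with melatonin had the same sign at all 4 times for 11895 of 20076 genes (59.2%). Signs symmetric about 0 and independent between times would give 12.5%, but neither condition is met. The median difference of all genes lay below 0 at 0, 1, 3 and 5 h (-0.08, -0.084, -0.103 and -0.091), and all 4 pairs share the slide row contrast. The excess therefore cannot be read as a melatonin effect. Among genes with several probes, an opposite probe was also called for 0, 52 and 125 of the called genes at 1, 3 and 5 h of LPS and for 85 of those called for melatonin. Of the panel, Il10 was well above background on 1 array and was not tested.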
